A study of Arabidopsis thaliana with 18 samples.

How the data were processed

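Transcript abundance was measured on Affymetrix ATH1 arrays, each of which carries sets of short probes (probe sets) that stand for genes. Per the labels, total RNA from root cultures of Arabidopsis thaliana Col-0 was extracted with a Qiagen RNeasy kit, labelled with biotin by a 3′ in vitro transcription protocol and hybridised with 1 sample per array. The cultures grew in B5 medium at 25 °C without light and were taken for the experiment at an age of 14 days. The labels name 6 groups, acetone, fenclorim and CMP at 4 h and at 24 h, with replicates 1 to 3 in each. Groups and replicate numbers were taken from the labels alone.

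The deposited values are intensity signals on a linear scale, 1 per probe set and array. Per the submitters' processing notes, the authors made them with the MAS5 algorithm in the GCOS software. The version of that software and the scaling target are not given in the sources used here. In the values, the mean of every array after trimming 2% of the probe sets at either end was 100.01, so the authors had scaled the arrays to a common trimmed mean. Signals were background-corrected by MAS5 and stayed above 0, with a lowest value of 0.0102 and a highest of 8886, and very low signals give large and uncertain fold changes. Detection calls were not used here. No pair of the 18 arrays held identical values, and all columns of the table were used.

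The table held 22810 probe sets, of which 64 were Affymetrix controls (9 hybridisation controls and 12 spiked poly-A controls among them) and were left out of the tests. Genes were named from the platform annotation given with the series. Of the other 22746 probe sets, 13513 were listed with 1 gene, 503 with several and 8730 were not listed, so they are unnamed here, and no name was taken from a probe set with several genes. Of the probe sets with 1 gene, 13436 matched a locus in the RefSeq gene table of assembly TAIR10.1, which was used only for names. Many genes of the array therefore stay unnamed, and a family described here holds only its named members. Where a gene had several probe sets, the one with the highest mean signal represents it. In the 6 comparisons of groups no gene of the 70 with several tested probe sets had probe sets called in opposite directions. Such a check needs at least 2 called probe sets of a gene. Against acetone 14 and 16 genes had them with fenclorim at 4 h and 24 h, and 11 and 14 with CMP. Between the compounds 0 genes had them at 4 h and 11 at 24 h. For the other genes the check says nothing.

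Signals were kept on the authors' scaling and transformed to log2. A probe set was tested if it lay above the 40th percentile of its array in at least 3 of the 18 arrays, which kept 15261. A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, so that the groups shared 1 estimate of the spread, and variances were moderated with an intensity trend. Contrasts compared each compound with acetone at each time, the compounds with each other at each time, the acetone groups between times, and the effects of each compound and their difference between times. P-values were adjusted by the Benjamini-Hochberg method over the tested probe sets, and a probe set was called at an adjusted p under 0.05. Intervals are at the 95% level. Array tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

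The design, the named-gene rule, 30 gene lists and all alternatives except those described as added were fixed before the data were examined. The rule took, in each comparison, the 8 largest increases and the 8 largest decreases among called probe sets with 1 named gene, a mean log2 signal above 5.75 (the 40th percentile) in the higher group and no overlap between the arrays of the groups, together with a fixed set of genes, of which GSTU25 and UGT73B4 were named in the annotation, and up to 4 members of each list with a call. Only part of the genes so taken is described, and that part was chosen after values and their stability had been seen. The planned lists held 457 loci, of which 83 were named on the array and 67 tested. Set tests were run for the 10 lists with at least 3 tested members and left out for the other 20. Of those 20, the root hair marker EXPA18 and the unfolded protein response gene BZIP60 are reported. So are NDB2 of the oxidative stress list, UGT78D1 of flavonoid synthesis and single transporters.

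Because so few planned genes could be named, 19 families were added from the annotation. They were drawn up after the annotation had been seen and before any fold change, except that the first lines of the value table had been seen when the mitochondrial list was written and that the plastid list was edited after fold changes had been seen. Lists were tested with camera, which compares the change of the members with that of all other tested probe sets, at a preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted within planned and added lists separately.

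The procedure was tested on simulated data: changes of log2 size 0.5, 1 or 2 were planted in 200 of 15261 probe sets. The spread of each probe set was pooled over all groups, and 1 draw was made per comparison. Between 1.01% and 6.02% of the calls were false, and between 0 and 2 of 30 lists without planted changes gave a set p under 0.05. The simulated noise was independent between probe sets, so these figures do not show how the tests behave where probe sets vary together. Each array is 1 sample, and the number of arrays limits the precision.

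Alternatives changed 1 choice at a time: quantile normalization, centring each array on its median, adding an offset of 3.81 (the 20th percentile of the signals) before the logarithm, no filter, a stricter filter at the 60th percentile (11134 probe sets), no intensity trend, a fit with only the compared groups, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. A fit without fenclorim 24 h replicate 2 and fenclorim 4 h replicate 3 together was added after seeing the data, because these arrays lay apart from their groups. For shared controls, 100 draws of unchanged groups were simulated. The split counts used all 10 splits of 3 against 3 arrays, or the real split with others drawn to make 100.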

Results

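Transcript levels were measured in root cultures of Arabidopsis thaliana, wild type Col-0, that had been grown in the dark in Gamborg's B5 medium and treated with fenclorim, with a second compound given only as CMP, or with the solvent acetone. Fenclorim is a dichlorinated phenylpyrimidine used as a safener, a compound that protects rice from herbicide injury. The labels do not expand the code name CMP and give no dose for either compound. Cultures were sampled after 4 h and 24 h, and each of the 6 groups had 3 ATH1 arrays, 18 in all. The series title names safening by fenclorim as its subject, and the design allows each compound to be set against its solvent and against the other at both times. The labels number the replicates but do not say that they were separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Changes are given as differences of mean log2 signal ± SE with n = 3 arrays per group, and a gene is said to have risen or fallen where its adjusted p from limma was under 0.05. Of 15261 probe sets tested, 8237 carried a gene name in the table used here and 7024 did not.

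The solvent separated from both compounds along the first principal component, which held 45.6% of the variance, and the second held 17.3%. In acetone the median signal per array was 37.6 ± 1.97 (SD, n = 3) at 4 h and 40.6 ± 0.244 at 24 h. It was 29.7 ± 1.42 and 29.0 ± 2.47 in fenclorim, and 30.8 ± 2.61 and 33.8 ± 1.44 in CMP. Within groups the mean correlation between arrays was lowest in the fenclorim 24 h group, at 0.908, and highest in the CMP 24 h group, at 0.973. On the second component, fenclorim 24 h replicate 2 lay at 4.21, beside the fenclorim 4 h replicates 1 and 2 at 1.66 and 11.0. Fenclorim 4 h replicate 3 lay at 52.4, toward the other fenclorim 24 h arrays at 72.7 and 75.5. CMP 4 h replicate 2 lay at 15.9 and the other CMP 4 h arrays at -30.4 and -41.2. The mean log2 signal of spiked poly-A controls was 7.21 in fenclorim 24 h replicate 2, against 7.83 and 8.04 in its group. It was 7.43 in fenclorim 4 h replicate 3, against 7.16 and 6.85, and 7.67 in CMP 4 h replicate 2, against 6.30 and 6.32. EXPA18, an expansin of root hair cells, was the marker of another cell type that could be tested. Its log2 signal was -0.22 in fenclorim 24 h replicate 2 and 3.70 and 4.05 in the other arrays of that group.

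**Figure D1:**
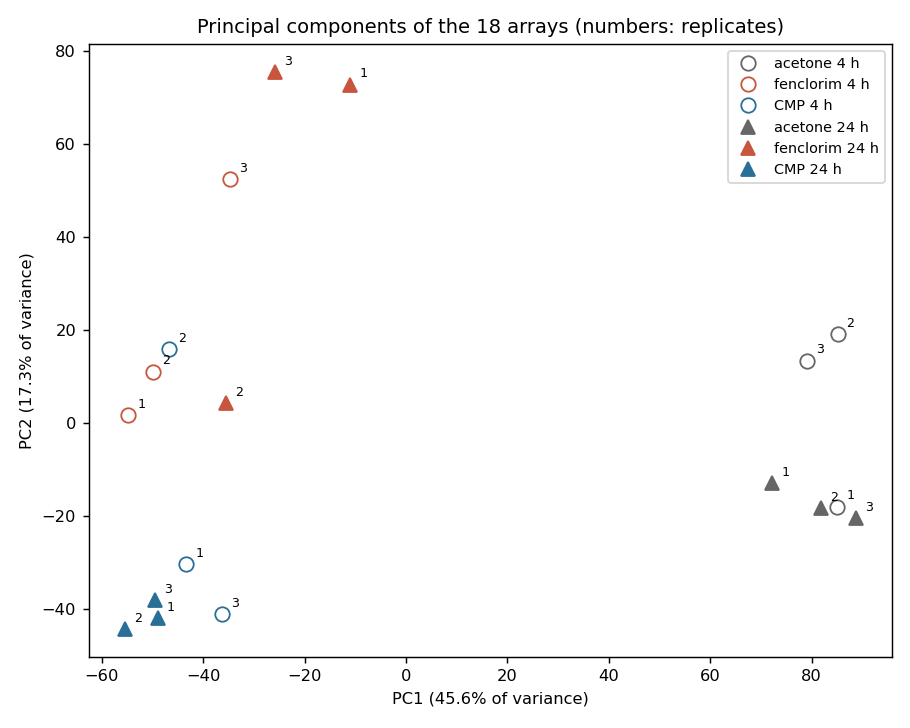
Principal components of the log2 signals of 15261 probe sets, the first (45.6% of the variance) on the x axis and the second (17.3%) on the y axis, in arbitrary units. Each point is 1 of 18 arrays, and the acetone arrays lie at the right, with fenclorim 24 h replicate 2 and fenclorim 4 h replicate 3 away from their groups.

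At 4 h of fenclorim, UGT73B4, a UDP-glycosyltransferase that attaches sugars to small molecules, was higher by 9.11 ± 0.74 (adjusted p = 9.29e-08), from a mean signal of 3.76 ± 5.14 (SD) in acetone to 991 ± 214 in fenclorim. Because the acetone signal was near the lowest values of the arrays, this change was smaller, 7.21, after adding an offset of 3.81 to every signal. Its relative UGT73B5 rose by 6.52 ± 0.30, the tau class glutathione transferase GSTU25 by 7.36 ± 0.57, and the aldo-keto reductase AT1G60750 by 7.79 ± 0.80. The alkenal reductase AER, which reduces reactive unsaturated carbonyls, rose by 4.48 ± 0.31. SBT3.3, a subtilase linked to immune priming, rose by 8.18 ± 0.51, the carboxylesterase-like AT1G68620 by 5.61 ± 0.25 and the beta-glucosidase BGLU28 by 5.83 ± 0.98. The acetone signals of AT1G60750 and SBT3.3 at 4 h also lay near the lowest values, and with the offset their changes were 5.41 and 6.62. Those of GSTU25 and BGLU28 were then 6.63 and 4.93. The organic cation transporter OCT5 rose by 4.49 ± 0.29 and NDB2, an alternative NAD(P)H dehydrogenase of mitochondria, by 3.80 ± 0.26. Among the genes that fell were the GDSL lipase AT1G29660 (-5.23 ± 0.45), the protein kinase WAG2 (-4.33 ± 0.69) and the expansin EXPA8 (-4.13 ± 0.62). The xyloglucan endotransglucosylases XTH16 (-3.81 ± 0.33) and XTH19 (-3.57 ± 0.33), which remodel the cell wall, fell as well. WAG2 was near the lowest signals in fenclorim, and its change with the offset was -3.40.

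By gene list, the planned UDP-glycosyltransferases had 8 higher and 1 lower of 16 (9 and 2 adjusted over the list alone, adjusted p = 5.45e-05, and adjusted p = 0.0139 with an estimated correlation). In the electrophile and oxylipin response list there were 5 higher and 0 lower of 6 (5 and 0 adjusted over the list alone, adjusted p = 9.84e-06, and adjusted p = 0.0139 with an estimated correlation). AER belongs to this list, which shares UGT73B4 and UGT73B5 with the glycosyltransferases and GSTU25 with the tau class. AT4G01870, a TolB-related protein outside the list, was at 6.29 ± 0.29. The tau class had 3 higher and 4 lower of 9 (3 and 4 adjusted over the list alone, adjusted p = 0.350, and adjusted p = 0.352 with an estimated correlation). GSTU25 rose and GSTU20 fell (-1.67 ± 0.41), and the median of the class, -0.31, turned to 0.03 when arrays were centred on their medians. WRKY and early defence signalling had 3 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, adjusted p = 0.00178, and adjusted p = 0.0142 with an estimated correlation), with the transcription factor WRKY6 at 3.18 ± 0.25. STZ, the zinc finger protein also known as ZAT10, was at 2.53 ± 0.18. Sulfur assimilation had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.0880 with an estimated correlation), and the sulfite reductase gene SIR rose by 1.54 ± 0.14. The P450 list had 2 higher and 0 lower of 3 (2 and 0 adjusted over the list alone, adjusted p = 0.0232, and adjusted p = 0.161 with an estimated correlation). In phenylpropanoid synthesis there were 2 higher and 0 lower of 3 (2 and 0 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.161 with an estimated correlation). Heat shock proteins had 1 higher and 0 lower of 3 (2 and 0 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.161 with an estimated correlation). The cell cycle list had 0 higher and 3 lower of 3 (0 and 3 adjusted over the list alone, adjusted p = 0.0284, and adjusted p = 0.146 with an estimated correlation). It holds the aurora kinase AUR1 (-1.50 ± 0.32) and PRL, a subunit of the replicative MCM helicase (-1.45 ± 0.21).

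Of 19 families drawn up from the annotation, 6 gave a set call in the same comparison, and only the named UDP-glycosyltransferases kept it with an estimated correlation. Tubulins, the subunits of microtubules, had 0 higher and 6 lower of 7 (adjusted p = 0.0116, and adjusted p = 0.279 with an estimated correlation). TUB1 was at -2.33 ± 0.28, TUB5 at -2.31 ± 0.20 and TUA1 at 0.26 ± 0.17, and after median centring 4 tubulins were lower and TUA1 was higher. Xyloglucan endotransglucosylases had 0 higher and 4 lower of 6 (adjusted p = 0.0178, and adjusted p = 0.271 with an estimated correlation). Trichome birefringence-like proteins, which act in the acetylation of wall polysaccharides, had 0 higher and 9 lower of 15 (adjusted p = 0.0410, and adjusted p = 0.133 with an estimated correlation), or 4 lower after median centring. Calmodulin-like proteins, which bind calcium, had 5 higher and 1 lower of 7 (adjusted p = 0.0178, and adjusted p = 0.133 with an estimated correlation), with CML37 at 2.82 ± 0.30 (2.20 with the offset). The ATG8 and related autophagy genes had 3 higher and 0 lower of 10 (adjusted p = 0.0410, and adjusted p = 0.271 with an estimated correlation), or 6 higher and 0 lower after median centring. Among all named UDP-glycosyltransferases there were 20 higher and 3 lower of 37 (adjusted p = 5.53e-08, and adjusted p = 0.00682 with an estimated correlation), or 22 higher and 1 lower after it. In total 2198 probe sets were higher and 3819 lower, of which 1387 and 2047 changed at least 2-fold. The higher share of the calls was 36.5%. It was 47.2% (2623 higher, 2933 lower) with quantile normalization and 66.5% (3474 higher, 1753 lower) with arrays centred on their medians. Simulated changes of log2 size 2 were recovered in 82.8% of cases, those of size 1 in 52.2% and those of size 0.5 in 10.4%. This and the recoveries given below use a spread pooled over all groups and 1 draw per comparison. They do not measure a difference in power between comparisons. The simulated data for this comparison gave 101 calls, against 6017 in the real data. With so few calls the adjusted threshold was stricter in the simulation, and the same holds for the comparisons below. The recoveries therefore do not give the power of the real comparisons.

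At 24 h of fenclorim UGT73B4 was higher than in acetone by 5.96 ± 0.74, UGT73B5 by 4.26 ± 0.30, and AT4G01870 by 5.23 ± 0.29. AT1G60750 was higher by 5.22 ± 0.80 (3.68 with the offset), AER by 4.23 ± 0.31 (adjusted p = 5.21e-08) and GSTU25 by 3.87 ± 0.57. ICL, the isocitrate lyase of the glyoxylate cycle, was higher by 5.93 ± 1.14, from acetone signals near the lowest in 2 of 3 arrays. With the offset its change was 4.50 and that of UGT73B4 5.29. SIR was 2.83-fold higher (95% interval of the log2 change 1.21 to 1.79). BGLU28 was higher by 3.78 ± 0.98, or 2.097 without fenclorim 24 h replicate 2. The transcription factor WRKY53 was lower (-2.32 ± 0.35), while WRKY6 (1.90 ± 0.25) and STZ (1.62 ± 0.18) were higher. Among the lower genes were XTH19 (-4.31 ± 0.33), EXPA8 (-3.84 ± 0.62), TUB1 (-3.52 ± 0.28) and TUB5 (-2.81 ± 0.20). So were TBL45 (-2.67 ± 0.26) and the calmodulin-binding IQD30 (-1.94 ± 0.28).

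Planned glycosyltransferases had 9 higher and 2 lower of 16 (9 and 2 adjusted over the list alone, adjusted p = 6.78e-05, and adjusted p = 0.0161 with an estimated correlation) at 24 h of fenclorim, or 10 higher and 0 lower after median centring. The electrophile list had 4 higher and 0 lower of 6 (4 and 0 adjusted over the list alone, adjusted p = 0.000123, and adjusted p = 0.0361 with an estimated correlation). WRKY and early defence signalling had 3 higher and 1 lower of 4 (3 and 1 adjusted over the list alone, adjusted p = 0.0425, and adjusted p = 0.108 with an estimated correlation). Phenylpropanoid synthesis had 2 higher and 0 lower of 3 (2 and 0 adjusted over the list alone, adjusted p = 0.0279, and adjusted p = 0.131 with an estimated correlation), with the cinnamoyl-CoA reductase CCR2 at 1.75 ± 0.30. The cell cycle list had 0 higher and 3 lower of 3 (0 and 3 adjusted over the list alone, adjusted p = 0.0425, and adjusted p = 0.131 with an estimated correlation). AUR1 was at -1.70 ± 0.32 and PRL at -1.28 ± 0.21, or -0.78 for PRL after median centring. No set call was made for the tau class, with 3 higher and 3 lower of 9 (4 and 3 adjusted over the list alone, adjusted p = 0.478). Nor was one made for the P450 list, with 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone, adjusted p = 0.674). Sulfur assimilation had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone, adjusted p = 0.0900), and heat shock proteins had 0 higher and 0 lower of 3 (0 and 0 adjusted over the list alone, adjusted p = 0.174). Median centring gave 4 higher and 0 lower for the tau class and 2 higher and 0 lower for heat shock proteins. The medians of the tau class and of the P450 list, -0.33 and -0.30, became 0.16 and 0.19 after median centring. From the annotation, all named UDP-glycosyltransferases had 20 higher and 3 lower of 37 (adjusted p = 3.21e-07, and adjusted p = 0.0103 with an estimated correlation), the only one of these families to keep its set call, or 24 higher and 0 lower after median centring. The ATG8 and related autophagy genes had 2 higher and 0 lower of 10 (adjusted p = 0.0133, and adjusted p = 0.180 with an estimated correlation), or 9 higher and 0 lower after it. Mitochondrially encoded genes had 7 higher and 0 lower of 13 (adjusted p = 0.000275, and adjusted p = 0.351 with an estimated correlation), or 12 higher and 0 lower after it, with nad6 of respiratory complex I at 1.47 ± 0.35. Tubulins had 1 higher and 6 lower of 7 (adjusted p = 0.0106, and adjusted p = 0.262 with an estimated correlation), or 4 lower after median centring. Xyloglucan endotransglucosylases had 0 higher and 5 lower of 6 (adjusted p = 0.0133, and adjusted p = 0.262 with an estimated correlation). Family 9 glycosyl hydrolases had 0 higher and 5 lower of 5 (adjusted p = 0.0162, and adjusted p = 0.351 with an estimated correlation). Trichome birefringence-like proteins had 0 higher and 8 lower of 15 (adjusted p = 0.0133, and adjusted p = 0.0843 with an estimated correlation), or 3 lower after median centring. EXPA18, of root hairs, was at -2.79 ± 0.83 (adjusted p = 0.0138), and at -1.43 without fenclorim 24 h replicate 2. Without acetone 24 h replicate 1 it was at -2.41, no longer past the threshold. At 4 h it was at -1.66 ± 0.83 (adjusted p = 0.125), and with the offset at -1.35 (adjusted p = 0.0409) there and -1.90 at 24 h.

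In this comparison 2160 probe sets were higher and 4230 lower, with 1014 and 2538 at 2-fold or more. The higher share was 33.8%, against 51.0% (2845 higher, 2738 lower) with quantile normalization and 74.7% (4786 higher, 1624 lower) with median centring, so the balance of directions depended on the scaling. Simulated changes of log2 size 2, 1 and 0.5 were recovered in 84.5%, 36.8% and 6.06% of cases. Only the arrays of the compared groups in the fit gave 2575 lower probe sets.

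At 4 h of CMP, the subtilase SBT3.3 was higher by 9.16 ± 0.51 (adjusted p = 1.10e-09), UGT73B4 by 7.44 ± 0.74, AT1G60750 by 7.28 ± 0.80 and GSTU25 by 6.69 ± 0.57. AT1G68620 was higher by 5.38 ± 0.25, AT4G01870 by 5.25 ± 0.29 and UGT73B5 by 4.95 ± 0.30. With the offset the changes of SBT3.3, UGT73B4 and AT1G60750 were 7.59, 5.55 and 4.91, and that of GSTU25 was 5.96. A pair of MATE transporters, which export organic compounds, rose as well, AT2G04050 by 5.27 ± 0.33 and AT2G04070 by 5.30 ± 0.39. The calmodulin-like genes CML37 and CML38 were higher by 5.09 ± 0.30 and 4.72 ± 0.48, or 4.36 and 4.12 with the offset. The mitochondrial small heat shock protein AT5G51440 rose by 4.56 ± 0.41, and BZIP60, a transcription factor of the unfolded protein response, by 2.31 ± 0.17. WAG2 (-4.32 ± 0.69), AT1G29660 (-3.99 ± 0.45), EXPA8 (-3.76 ± 0.62) and the hydroxycinnamoyl transferase HCT of lignin synthesis (-1.70 ± 0.16) were lower. WAG2 was near the lowest signals in 1 CMP array, and its change with the offset was -3.28.

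Among planned lists, the glycosyltransferases had 7 higher and 3 lower of 16 (7 and 3 adjusted over the list alone, adjusted p = 0.00204, and adjusted p = 0.0387 with an estimated correlation) at 4 h of CMP, or 7 higher and 1 lower after median centring. For the electrophile list the counts were 4 higher and 1 lower of 6 (4 and 1 adjusted over the list alone, adjusted p = 0.000513, and adjusted p = 0.0387 with an estimated correlation). WRKY and early defence signalling had 3 higher and 0 lower of 4 (4 and 0 adjusted over the list alone, adjusted p = 2.60e-05, and adjusted p = 0.00455 with an estimated correlation). WRKY6 was at 3.56 ± 0.25, STZ at 3.31 ± 0.18 and WRKY22 at 2.42 ± 0.19. The lower member of the electrophile list was AOR, an alkenal oxidoreductase of plastids, at -0.77 ± 0.22. Its call was lost without acetone 4 h replicate 2 (-0.62), without CMP 4 h replicate 3 (-0.63) and after median centring (-0.48). Heat shock proteins had 3 higher and 0 lower of 3 (3 and 0 adjusted over the list alone, adjusted p = 0.00214, and adjusted p = 0.0921 with an estimated correlation). The P450 list had 2 higher and 0 lower of 3 (3 and 0 adjusted over the list alone, adjusted p = 0.0114, and adjusted p = 0.209 with an estimated correlation). No set call was made for the tau class, with 3 higher and 4 lower of 9 (3 and 4 adjusted over the list alone, adjusted p = 0.521) (3 higher and 2 lower after median centring), or phenylpropanoid synthesis, with 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone, adjusted p = 0.960). Sulfur assimilation had 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone, adjusted p = 0.607), and the cell cycle list had 0 higher and 1 lower of 3 (0 and 2 adjusted over the list alone, adjusted p = 0.218). From the annotation, calmodulin-like proteins had 5 higher and 0 lower of 7 (adjusted p = 2.80e-05, and adjusted p = 0.0188 with an estimated correlation). Named glycosyltransferases had 18 higher and 4 lower of 37 (adjusted p = 2.80e-05, and adjusted p = 0.0188 with an estimated correlation), or 18 higher and 2 lower after median centring. Expansins had 0 higher and 9 lower of 12 (adjusted p = 0.0164, and adjusted p = 0.426 with an estimated correlation), or 0 higher and 6 lower after it, and tubulins had 0 higher and 6 lower of 7 (adjusted p = 0.00806, and adjusted p = 0.282 with an estimated correlation). The ATG8 and related autophagy genes had 5 higher and 0 lower of 10 (adjusted p = 0.0101, and adjusted p = 0.140 with an estimated correlation). Heat shock proteins and co-chaperones had 4 higher and 1 lower of 11 (adjusted p = 0.0268, and adjusted p = 0.378 with an estimated correlation). EXPA18 was at -1.74 ± 0.83 (adjusted p = 0.111), or -1.41 (adjusted p = 0.0345) with the offset. In total 2110 probe sets were higher and 3559 lower, with 1464 and 1724 at 2-fold or more. The higher share was 37.2%, against 46.3% (2474 higher, 2872 lower) with quantile normalization and 65.1% (3009 higher, 1612 lower) with median centring. The simulation recovered 79.0%, 33.8% and 5.71% of changes of log2 size 2, 1 and 0.5.

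After 24 h of CMP, AT2G38240, an oxygenase that acts on jasmonic acid, was higher by 6.67 ± 0.69 (adjusted p = 1.30e-06), the U-box ubiquitin ligase AT3G61390 by 6.20 ± 0.51 and AT1G68620 by 5.93 ± 0.25. AT1G60750 was higher by 5.84 ± 0.80 (4.28 with the offset), SBT3.3 by 5.70 ± 0.51 and CML37 by 5.16 ± 0.30. UGT73B4 was higher by 3.81 ± 0.74, UGT73B5 by 2.69 ± 0.30, AER by 1.37 ± 0.31 and ICL by 4.38 ± 1.14. In acetone at 24 h AT2G38240 and ICL were near the lowest signals in 2 of 3 arrays, and with the offset their changes were 5.47 and 2.97, and that of UGT73B4 3.18. GSTU25 was at 1.63 ± 0.57 (adjusted p = 0.0281), and its call was lost without acetone 24 h replicate 3 (1.09), CMP 24 h replicate 1 (1.52) or CMP 24 h replicate 2 (1.52). EXPA8 (-5.22 ± 0.62), AT1G29660 (-4.14 ± 0.45), WAG2 (-3.90 ± 0.69) and XTH19 (-3.32 ± 0.33) were lower. EXPA8 and WAG2 each had 1 CMP array near the lowest signals, and with the offset they were at -4.47 and -3.02. So were TUB1 (-3.21 ± 0.28), TUB5 (-3.20 ± 0.20), GSTU20 (-2.35 ± 0.41) and AOR (-1.78 ± 0.22).

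For WRKY and early defence signalling, 24 h of CMP gave 3 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, adjusted p = 0.0102, and adjusted p = 0.0594 with an estimated correlation). No other planned list gave a set call. Glycosyltransferases had 6 higher and 3 lower of 16 (6 and 5 adjusted over the list alone, adjusted p = 0.217), or 7 higher and 1 lower after median centring, and the electrophile list had 4 higher and 1 lower of 6 (5 and 1 adjusted over the list alone, adjusted p = 0.166). The tau class had 1 higher and 2 lower of 9 (1 and 2 adjusted over the list alone, adjusted p = 0.961), and its median of -0.16 turned to 0.11 after median centring. The P450 list had 2 higher and 0 lower of 3 (2 and 0 adjusted over the list alone, adjusted p = 0.294). Sulfur assimilation had 1 higher and 3 lower of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.608), or 1 higher and 1 lower after median centring. Phenylpropanoid synthesis had 2 higher and 1 lower of 3 (2 and 1 adjusted over the list alone, adjusted p = 0.590). Heat shock proteins had 1 higher and 0 lower of 3 (0 and 0 adjusted over the list alone, adjusted p = 0.265). The cell cycle list had 0 higher and 2 lower of 3 (0 and 2 adjusted over the list alone, adjusted p = 0.219). From the annotation, ATG8 and related autophagy genes had 7 higher and 0 lower of 10 (adjusted p = 0.000167, and adjusted p = 0.0309 with an estimated correlation), with ATG8H at 2.65 ± 0.36. Trichome birefringence-like proteins had 0 higher and 8 lower of 15 (adjusted p = 0.00384, and adjusted p = 0.0309 with an estimated correlation). IQD calmodulin-binding proteins had 0 higher and 7 lower of 10 (adjusted p = 0.00598, and adjusted p = 0.0425 with an estimated correlation), with IQD30 at -1.99 ± 0.28. Tubulins had 0 higher and 6 lower of 7 (adjusted p = 0.00268, and adjusted p = 0.188 with an estimated correlation). Expansins had 0 higher and 8 lower of 12 (adjusted p = 0.00950, and adjusted p = 0.368 with an estimated correlation). Xyloglucan endotransglucosylases had 0 higher and 4 lower of 6 (adjusted p = 0.0103, and adjusted p = 0.197 with an estimated correlation). Family 9 glycosyl hydrolases had 0 higher and 2 lower of 5 (adjusted p = 0.0300, and adjusted p = 0.368 with an estimated correlation). Named glycosyltransferases had 14 higher and 7 lower of 37 (adjusted p = 0.00950, and adjusted p = 0.115 with an estimated correlation), or 20 higher and 3 lower after median centring. Calmodulin-like proteins had 4 higher and 1 lower of 7 (adjusted p = 0.0103, and adjusted p = 0.114 with an estimated correlation). EXPA18 was at -1.73 ± 0.83 (adjusted p = 0.104), or -1.45 (adjusted p = 0.0266) with the offset. In total 2638 probe sets were higher and 3929 lower, with 1543 and 2313 at 2-fold or more. The higher share was 40.2%, against 47.6% (3183 higher, 3504 lower) with quantile normalization and 61.4% (3937 higher, 2476 lower) with median centring. The simulation recovered 82.4%, 30.9% and 6.49% of changes of log2 size 2, 1 and 0.5.

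**Figure D2:**
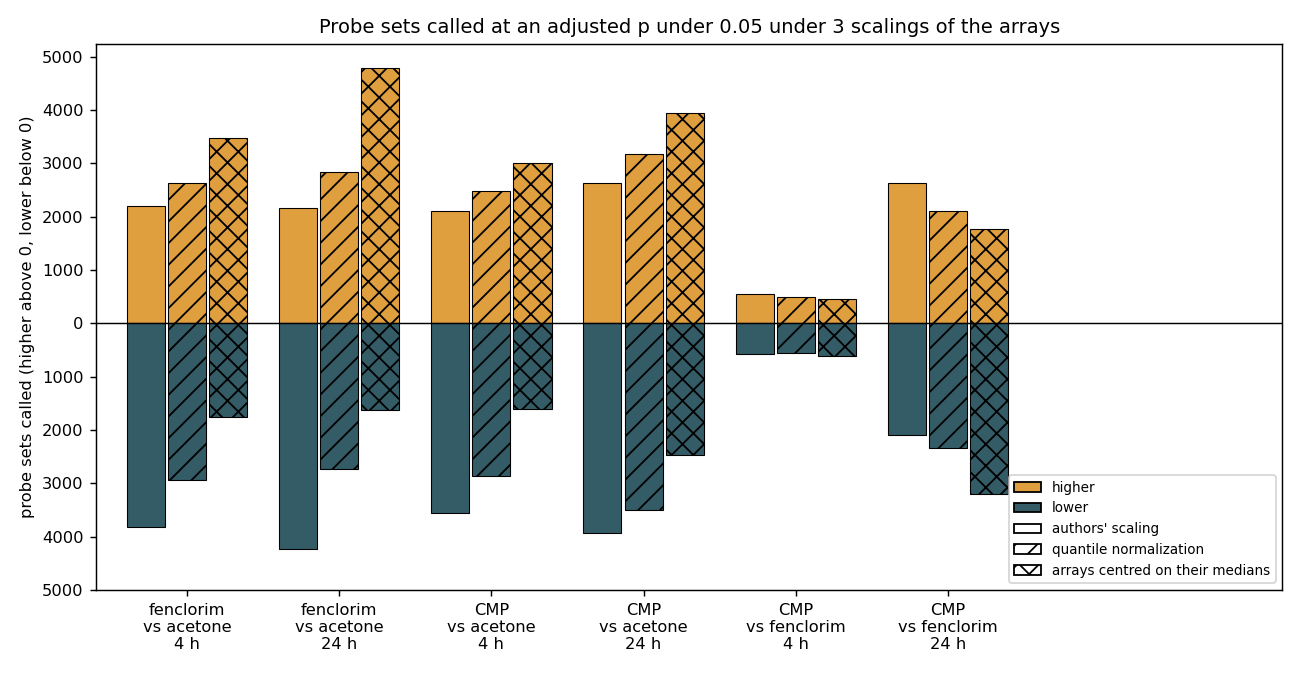
Numbers of probe sets called higher (above 0) and lower (below 0) in 6 comparisons, with the authors' scaling, quantile normalization and median centring side by side. With the authors' scaling the lower calls outnumbered the higher ones in the 4 comparisons with acetone, and after median centring the higher calls outnumbered the lower ones in all 4.

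Against the authors' scaling, quantile normalization moved the median change of all probe sets by 0.15 and 0.21 for fenclorim at 4 h and 24 h, by 0.13 and 0.12 for CMP, and by -0.02 and -0.11 for CMP against fenclorim, on the log2 scale. Median centring moved it by 0.34, 0.49, 0.29, 0.27, -0.05 and -0.22. The genes named above with changes of several log2 units exceed these shifts, while smaller changes, such as TUA1 at 0.50 ± 0.17 for fenclorim at 24 h, are of their size.

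The compounds were then compared directly at 4 h. CMP cultures had less BGLU28 (-4.95 ± 0.98, adjusted p = 0.00470), less of the isoflavone reductase-like gene AT1G75280 (-2.76 ± 0.39), and less AER (-2.01 ± 0.31) than fenclorim cultures. SIR (-1.78 ± 0.14), HCT (-1.74 ± 0.16), OCT5 (-1.58 ± 0.29) and UGT73B5 (-1.57 ± 0.30) were lower as well. They had more AT2G04070 (2.54 ± 0.39), AT3G61390 (2.53 ± 0.51), CML37 (2.27 ± 0.30), AT2G04050 (1.79 ± 0.33), XTH19 (1.79 ± 0.33), WRKY22 (1.64 ± 0.19) and CML41 (1.61 ± 0.34). Several of the genes with the largest changes against acetone did not differ past the threshold, among them GSTU25 (95% interval -1.86 to 0.53), UGT73B4 (-3.24 to -0.10), AT1G60750 (-2.20 to 1.17), and AT1G68620 (-0.75 to 0.29). The same was so for SBT3.3 (-0.10 to 2.04), WAG2 (-1.44 to 1.46) and TBL45 (-0.49 to 0.62). UGT73B4 and SBT3.3 passed it with an offset added (-1.66 and 0.97) or with only the compared arrays (-1.67 and 0.97).

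In 5 planned lists the compounds differed with both correlations. With CMP, sulfur assimilation had 0 higher and 2 lower of 5 (0 and 4 adjusted over the list alone, adjusted p = 6.78e-05, and adjusted p = 0.00620 with an estimated correlation). The electrophile list had 0 higher and 2 lower of 6 (0 and 5 adjusted over the list alone, adjusted p = 0.000321, and adjusted p = 0.0329 with an estimated correlation). The glycosyltransferases had 0 higher and 4 lower of 16 (0 and 5 adjusted over the list alone, adjusted p = 0.00477, and adjusted p = 0.0363 with an estimated correlation). Phenylpropanoid synthesis had 0 higher and 2 lower of 3 (0 and 3 adjusted over the list alone, adjusted p = 0.000333, and adjusted p = 0.0363 with an estimated correlation). WRKY and early defence signalling had 2 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, adjusted p = 0.000473, and adjusted p = 0.0129 with an estimated correlation). Heat shock proteins had 0 higher and 0 lower of 3 (3 and 0 adjusted over the list alone, adjusted p = 0.0267, and adjusted p = 0.193 with an estimated correlation), and the tau class had 0 higher and 0 lower of 9 (0 and 0 adjusted over the list alone, adjusted p = 0.675). From the annotation, calmodulin-like proteins had 4 higher and 0 lower of 7 (adjusted p = 0.000166, and adjusted p = 0.0319 with an estimated correlation). Xyloglucan endotransglucosylases had 3 higher and 0 lower of 6 (adjusted p = 0.00792, and adjusted p = 0.304 with an estimated correlation). Heat shock proteins and co-chaperones had 2 higher and 0 lower of 11 (adjusted p = 0.0169, and adjusted p = 0.707 with an estimated correlation). Named glycosyltransferases had 0 higher and 5 lower of 37 (adjusted p = 0.00491, and adjusted p = 0.134 with an estimated correlation). Mitochondrially encoded genes had 0 higher and 1 lower of 13 (adjusted p = 0.0143, and adjusted p = 0.938 with an estimated correlation). In total 543 probe sets were higher with CMP and 575 lower, with 350 and 363 at 2-fold or more. The counts were 254 and 337 without CMP 4 h replicate 1 and 290 and 348 without CMP 4 h replicate 3. They were 352 and 379 without fenclorim 4 h replicate 1 and 272 and 315 without fenclorim 4 h replicate 2. Without fenclorim 4 h replicate 3 and fenclorim 24 h replicate 2, the arrays that lay apart, 947 were higher. The simulation recovered 82.8%, 34.7% and 6.25% of changes of log2 size 2, 1 and 0.5.

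At 24 h more probe sets separated the compounds. CMP cultures had more AT3G61390 (4.41 ± 0.51, adjusted p = 2.77e-05), AT2G38240 (3.67 ± 0.69), and CML38 (3.04 ± 0.48). CML37 (2.80 ± 0.30), ATG8H (2.24 ± 0.36) and WRKY22 (1.05 ± 0.19) were higher as well. They had less AT1G75280 (-3.11 ± 0.39), AER (-2.87 ± 0.31), OCT5 (-2.68 ± 0.29), GSTU25 (-2.24 ± 0.57) and SIR (-1.85 ± 0.14). UGT74D1 (-2.17 ± 0.24) and IAGLU (-1.67 ± 0.22), glycosyltransferases that act on auxins, were lower. So were HCT (-1.58 ± 0.16), UGT73B5 (-1.57 ± 0.30), AOR (-1.39 ± 0.22) and BZIP60 (-0.86 ± 0.17). BGLU28 was at -2.95 ± 0.98 (adjusted p = 0.0315), and its call was lost without fenclorim 24 h replicate 2 (-1.27) and without each of CMP 24 h replicates 1, 2 and 3 (-3.09, -2.96 and -2.81). No difference passed the threshold for AT1G60750 (95% interval -1.06 to 2.31), ICL (-3.96 to 0.84), WAG2 (-2.52 to 0.38), TBL45 (-0.88 to 0.23), PRL (-0.57 to 0.33) or IQD30 (-0.65 to 0.55).

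At 24 h the planned glycosyltransferases had 0 higher and 8 lower of 16 (0 and 8 adjusted over the list alone, adjusted p = 0.00612, and adjusted p = 0.0520 with an estimated correlation) with CMP against fenclorim. The electrophile list had 0 higher and 5 lower of 6 (0 and 5 adjusted over the list alone, adjusted p = 0.00233, and adjusted p = 0.0520 with an estimated correlation). Sulfur assimilation had 0 higher and 3 lower of 5 (0 and 3 adjusted over the list alone, adjusted p = 0.0220, and adjusted p = 0.0520 with an estimated correlation). WRKY and early defence signalling had 2 higher and 0 lower of 4 (3 and 0 adjusted over the list alone, adjusted p = 0.0220, and adjusted p = 0.0520 with an estimated correlation). None of these 4 set calls held with an estimated correlation. The tau class had 0 higher and 3 lower of 9 (0 and 3 adjusted over the list alone, adjusted p = 0.349), and phenylpropanoid synthesis had 1 higher and 1 lower of 3 (1 and 2 adjusted over the list alone, adjusted p = 0.236). From the annotation, named glycosyltransferases had 2 higher and 13 lower of 37 (adjusted p = 0.0235, and adjusted p = 0.354 with an estimated correlation). The ATG8 and related autophagy genes had 5 higher and 0 lower of 10 (adjusted p = 0.0339, and adjusted p = 0.354 with an estimated correlation), or 3 higher and 0 lower after median centring. Plastid-encoded genes had 0 higher and 9 lower of 51 (adjusted p = 0.0235, and adjusted p = 0.551 with an estimated correlation), or 0 higher and 14 lower after it, and mitochondrially encoded genes had 0 higher and 3 lower of 13 (adjusted p = 0.0315, and adjusted p = 0.551 with an estimated correlation). The auxin response list, with 4 tested members, gave adjusted p-values between 0.0845 and 0.880 over the 6 comparisons. None of the 6 comparisons of groups gave a set call in 7 other families, the glutathione transferases, CYP71B P450s, beta-glucosidases, U-box ligases, SWEET transporters, RALF-like peptides and serine carboxypeptidase-like proteins. Their lowest adjusted p in these comparisons was 0.0660, for the last at 4 h of CMP. EXPA18 did not differ past the threshold (95% interval -0.69 to 2.81). The calls numbered 2626 higher and 2088 lower, with 1546 and 794 at 2-fold or more. The higher share was 55.7%, against 47.3% (2097 higher, 2338 lower) with quantile normalization and 35.5% (1767 higher, 3205 lower) with median centring. Without fenclorim 24 h replicate 1 the counts were 1542 and 1340. The higher count was 1660 without CMP 24 h replicate 1 and 1682 without CMP 24 h replicate 2, and it was 4099 without the fenclorim arrays that lay apart. The simulation recovered 87.0%, 43.5% and 12.9% of changes of log2 size 2, 1 and 0.5.

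**Figure D3:**
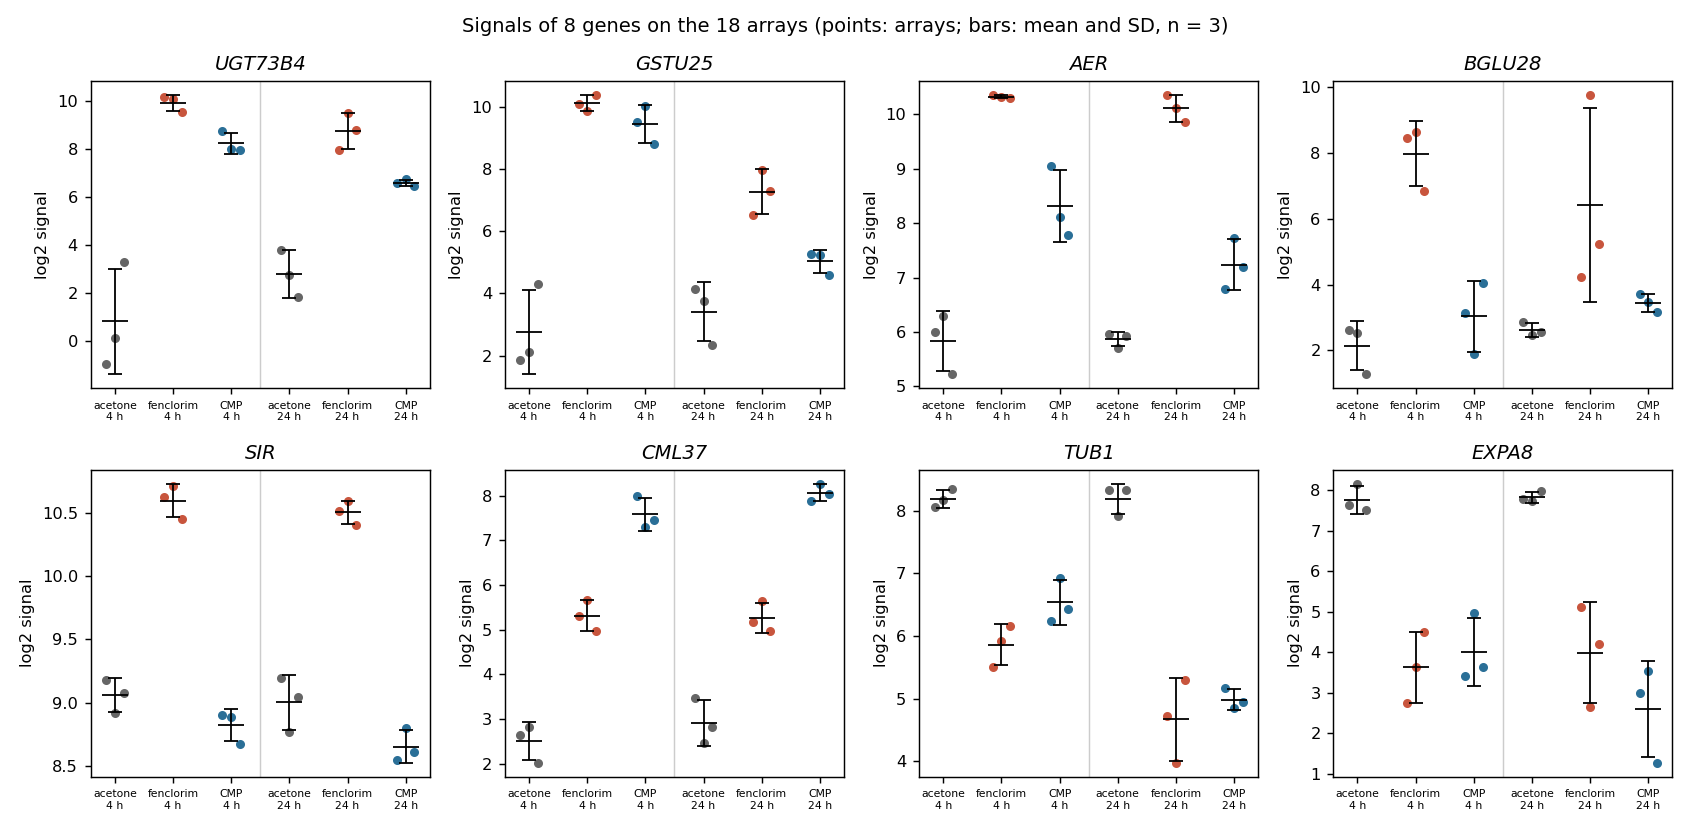
Log2 signal on the y axis for 8 genes, by group on the x axis, with arrays as points and the mean and SD of each group as bars (n = 3). UGT73B4, GSTU25 and CML37 lie above acetone in every treated group, SIR lies above it with fenclorim, EXPA8 and TUB1 lie below it, and BGLU28 spreads widely in fenclorim at 24 h.

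Across probe sets, the changes against acetone under fenclorim and CMP had a correlation of 0.839 (Spearman's rho 0.808) at 4 h and of 0.707 (rho 0.654) at 24 h, over genes, which are not independent replicates. At 4 h, 1600 probe sets were higher and 2499 lower with both compounds, where independent lists of these sizes would share 304 and 891, and 22 were called in opposite directions. At 24 h the shared calls were 1383 higher and 2318 lower, where independent lists would share 373 and 1089, with 82 opposite. UGT73B4, SBT3.3, AT1G60750 and AT1G68620 were higher and AT1G29660, WAG2, EXPA8 and TBL45 lower with both compounds at both times. Both comparisons at a time use the same 3 acetone arrays. Simulated unchanged groups set against a shared simulated control gave correlations of 0.455 on average and up to 0.891 at 4 h. At 24 h the values were 0.429 and up to 0.880, each over 100 draws. The simulated controls drew on the spread of all groups, so this range need not be what the 3 acetone arrays would give. These simulated groups shared at most 1 higher and 0 lower calls at 4 h, and none at 24 h. Because they held no real change, these counts do not show how many shared calls the common controls add where changes are real. The covariance was 1.02 at 4 h, against a simulated mean of 0.0632 and a highest value of 0.282, and 0.834 at 24 h, against 0.0605 and 0.224. With 3 acetone arrays per time the controls could not be split with 2 on either side, and part of the correlation may come from the shared controls.

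**Figure D4:**
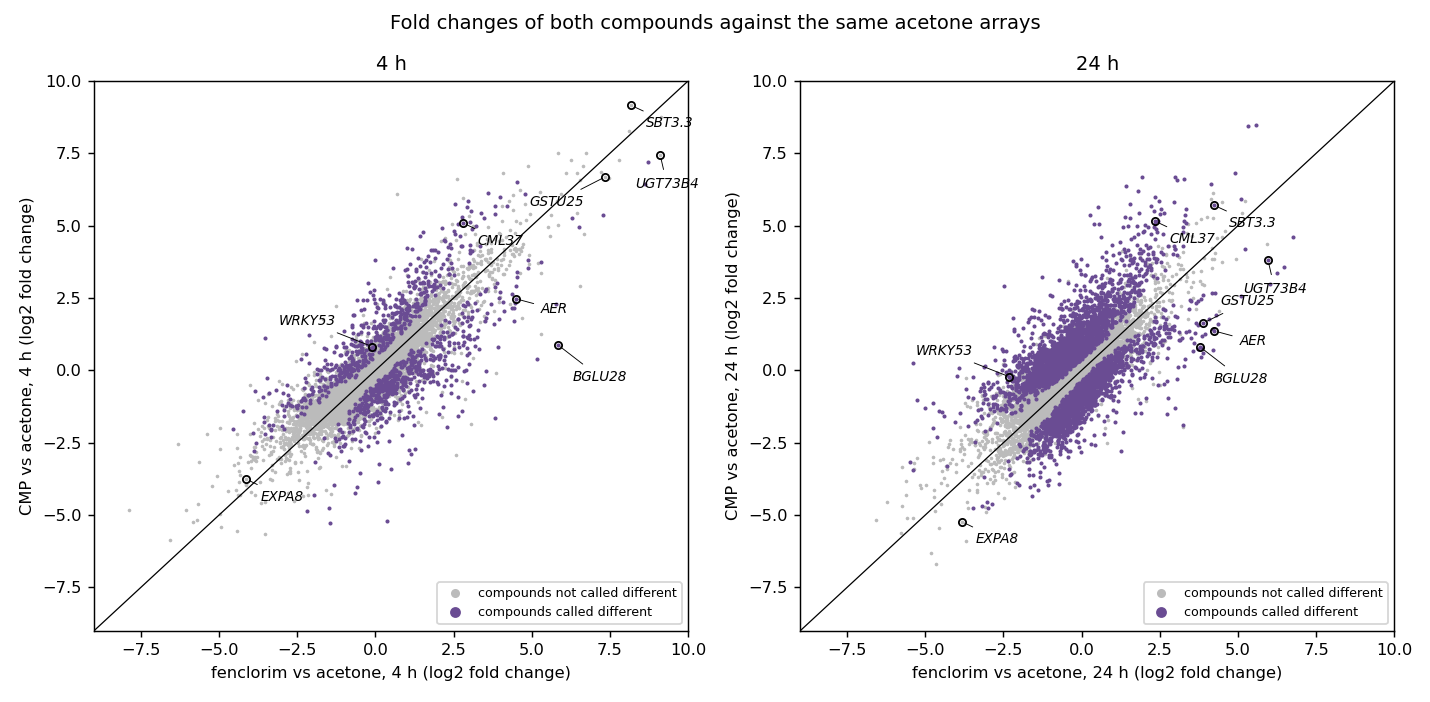
Log2 fold changes against acetone with fenclorim (x axis) and CMP (y axis) for 15261 probe sets (4 h left, 24 h right), with a line of equal change and 8 named genes ringed. Coloured points are the probe sets called different between the compounds, 1118 at 4 h and 4714 at 24 h, and they lie on both sides of the line.

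The design also asks whether an effect differed between the times. The fenclorim effect at 24 h minus that at 4 h was called higher for 153 probe sets and lower for 266. For NDB2 (-1.99 ± 0.37), SBT3.3 (-3.94 ± 0.72) and UGT73B5 (-2.26 ± 0.42) the difference from acetone was smaller at 24 h. Most of the value for SBT3.3 comes from its acetone signal, near the lowest values at 4 h and at 2.80 ± 0.51 for 24 h against 4 h, and with the offset it was -2.67. These 3 calls were lost with only the compared arrays in the fit. The CMP effect differed for 128 and 337 probe sets. It was smaller at 24 h for GSTU25 (-5.07 ± 0.80), AT2G04050 (-3.80 ± 0.47), AT5G51440 (-3.79 ± 0.58), AT2G04070 (-3.21 ± 0.55), UGT73B5 (-2.26 ± 0.42) and NDB2 (-1.91 ± 0.37). By planned list, the CMP effect at 24 h was lower than at 4 h for the electrophile list, with 0 higher and 2 lower of 6 (0 and 5 adjusted over the list alone, adjusted p = 0.000101, and adjusted p = 0.0273 with an estimated correlation), and for WRKY and early defence signalling, with 0 higher and 1 lower of 4 (0 and 2 adjusted over the list alone, adjusted p = 0.00190, and adjusted p = 0.0273 with an estimated correlation). The glycosyltransferases had 0 higher and 2 lower of 16 (0 and 3 adjusted over the list alone, adjusted p = 0.00964, and adjusted p = 0.0774 with an estimated correlation), and heat shock proteins had 0 higher and 1 lower of 3 (0 and 1 adjusted over the list alone, adjusted p = 0.00834, and adjusted p = 0.137 with an estimated correlation). The fenclorim effect was lower at 24 h for the P450 list, with 0 higher and 1 lower of 3 (0 and 3 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.257 with an estimated correlation). The electrophile list had 0 higher and 2 lower of 6 (0 and 3 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.188 with an estimated correlation), and WRKY and early defence signalling had 0 higher and 1 lower of 4 (0 and 3 adjusted over the list alone, adjusted p = 0.0144, and adjusted p = 0.134 with an estimated correlation). In the added families the time contrasts gave 13 set calls, none of them kept with an estimated correlation. Of these, 4 fell in families without a call between groups, CYP71B P450s (adjusted p = 0.0176) and U-box ligases (adjusted p = 0.0483), lower for the fenclorim effect, and beta-glucosidases (adjusted p = 0.0468, higher) and RALF-like peptides (adjusted p = 0.0468, lower) for the difference between the compounds. The difference between the compounds changed with time for 278 and 472 probe sets, among them AT2G04050 (-2.38 ± 0.47) and BZIP60 (-1.57 ± 0.24). The CMP minus fenclorim difference of AT2G04050 was 1.79 ± 0.33 at 4 h and -0.58 ± 0.33 at 24 h, and that of BZIP60 was 0.72 ± 0.17 and -0.86 ± 0.17. The higher share of these calls was 37.1%, against 32.5% (238 higher, 495 lower) with quantile normalization and 26.9% (204 higher, 553 lower) with median centring. With only the compared arrays in the fit, the counts of the time contrasts fell for fenclorim and for the difference between the compounds, and rose for CMP. Single arrays moved the counts by over 1.5 times, and in the following fits each was left out in turn. For fenclorim, the higher and lower counts were 97 and 226, and 58 and 140, without acetone 4 h replicates 1 and 2. Without acetone 24 h replicates 1, 2 and 3 they were 70 and 118, 57 and 125, and 84 and 216. Without fenclorim 4 h replicates 1, 2 and 3 they were 46 and 100, 54 and 108, and 387 and 508, and without fenclorim 24 h replicates 1, 2 and 3 they were 74 and 152, 772 and 1351, and 73 and 172. For CMP, they were 56 and 126 without CMP 4 h replicate 1, and 57 and 126, 62 and 178, and 63 and 194 without CMP 24 h replicates 1, 2 and 3. Without acetone 4 h replicate 3 they were 54 and 147, and without acetone 24 h replicates 2 and 3 they were 70 and 180, and 53 and 147. For the difference between the compounds, they were 128 and 237, and 111 and 236, without CMP 4 h replicates 1 and 2. Without CMP 24 h replicates 1, 2 and 3 they were 94 and 172, 125 and 265, and 96 and 239. Without fenclorim 4 h replicates 1, 2 and 3 they were 72 and 139, 70 and 151, and 682 and 880, and without fenclorim 24 h replicates 1 and 2 they were 106 and 197, and 1764 and 1255.

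In acetone itself limma called 0 probe sets between 24 h and 4 h, with 769 at an unadjusted p under 0.05, and no other tool was run on single probe sets. By set test at the preset correlation, 4 lists shifted without a call of any member, plastid-encoded genes down (adjusted p = 9.10e-09, and adjusted p = 0.653 with an estimated correlation) and mitochondrially encoded genes down (adjusted p = 2.14e-06, and adjusted p = 0.653 with an estimated correlation), calmodulin-like proteins up (adjusted p = 0.00587, and adjusted p = 0.210 with an estimated correlation) and the electrophile list up (adjusted p = 0.0334, and adjusted p = 0.221 with an estimated correlation). None of these set calls was kept with an estimated correlation. The median change of mitochondrially encoded genes in acetone was -0.39, and their higher signals at 24 h of fenclorim are measured against that lower level. SBT3.3 was at 2.80 ± 0.51 (adjusted p = 0.108), and GSTU25, UGT73B5 and NDB2 were at 0.65 ± 0.57, 0.49 ± 0.30 and 0.26 ± 0.26 in acetone at 24 h against 4 h. Their 95% intervals were -0.55 to 1.85, -0.14 to 1.12 and -0.29 to 0.81, and the root hair marker EXPA18 was at 0.34 ± 0.83. ICL was at -4.70 ± 1.14 (adjusted p = 0.418), so its increases at 24 h stand against a lower acetone signal than at 4 h, near the lowest values in 2 of 3 arrays, though that difference did not pass the threshold. Without acetone 4 h replicate 1, 7 probe sets were called higher and 3 lower. Without acetone 4 h replicate 3, 7 were higher, and the other fits that left out 1 array called at most 2.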

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

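Of the tests in this part, those on exchanged labels, RNA integrity, spiked controls, the lean toward lower calls, the calls between times within a compound and the contrast between 24 h and 4 h of the compound comparison were chosen after the results had been seen. The counts over other splits and the test of the authors' scaling on the arrays that lay apart were planned.

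Effects that differed between the times, by a test of the difference itself, drew attention for 153 higher and 266 lower probe sets with fenclorim, for 128 and 337 with CMP and for 278 and 472 in the difference between the compounds. With fenclorim the differences (24 h effect minus 4 h effect, log2) were -2.60 for AT5G51440, -3.49 for GSTU25, -1.99 for NDB2, -3.94 for SBT3.3, -2.26 for UGT73B5 and -2.21 for WRKY53. With CMP they were -3.80 for AT2G04050, -3.21 for AT2G04070, -3.79 for AT5G51440, -1.18 for BZIP60, -5.07 for GSTU25, -1.26 for IAGLU, -1.91 for NDB2, -1.65 for OCT5, -3.46 for SBT3.3, -1.22 for STZ, -1.55 for TUB1, -1.29 for TUB5 and -2.26 for UGT73B5, and on the other side 4.19 for AT2G38240 and 6.37 for ICL. Most of both values for SBT3.3 comes from its acetone signal, near the lowest values at 4 h. Most of that for ICL likewise comes from its acetone signal, near the lowest values at 24 h, and this call was lost with the offset (4.51) and in 10 of 12 fits that left out 1 array. With the offset AT2G38240 was at 3.48, and its call was lost in 9 of 12 such fits. The compounds differed in their change with time by -2.38 for AT2G04050, -1.57 for BZIP60, -1.24 for UGT74D1, -1.73 for XTH16, 3.55 for AT2G38240 and 1.96 for ATG8H. Of these 27 gene calls, 12 held in every fit that left out 1 array and 11 in every other alternative, and 8 held in both, namely AT2G04050 in both contrasts with CMP, AT2G04070, AT5G51440, GSTU25, NDB2 and UGT73B5 with CMP and BZIP60 in the difference between the compounds.

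Other splits of the arrays were counted. Any split of 3 with 3 arrays other than the real one mixes the groups. A real difference then enters the spread and lowers the calls, so low counts there do not show what unchanged groups would give. For the comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05: the real and the highest other counts were 6017 and 0 for fenclorim at 4 h, 6390 and 0 at 24 h, 5669 and 0 for CMP at 4 h, 6567 and 0 at 24 h, 1118 and 0 between the compounds at 4 h and 4714 and 1 at 24 h, with the real split alone (1 of 10) as large, and 0 and 2 in acetone between the times, where all 10 splits were as large. For the time contrasts, 100 splits were counted, the real one and drawn ones that move arrays of a treatment between the times. Within CMP 1809 and within fenclorim 1445 probe sets were called between the times, so such splits keep real effects of time, and they do not decide whether chance can be excluded. For the time difference of the CMP effect, 4 of 100 splits, the real one included, gave at least the real 465 calls. The highest other split, with 1397, exchanged acetone replicates 1 and 2 between the times. For the fenclorim effect 8 of 100 splits gave at least 419. The highest other split there, with 2896, exchanged fenclorim 24 h replicate 2 with fenclorim 4 h replicate 3. For the difference between the compounds 5 of 100 splits gave at least 750, and the highest other, with 2404, exchanged all CMP arrays between the times, which turns the contrast into a sum of the time effects of both compounds. For the single compounds the highest other split called several times the real count, which points to a structure of the samples whose cause these counts do not show.

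The first pattern is that fenclorim 24 h replicate 2 and fenclorim 4 h replicate 3 lay apart from their groups. Against exchanged labels, the probe sets whose CMP effect changed with time gave the 24 h array a score of -0.1448, between the other 24 h arrays (-0.3395 and 0.1184) and away from the fenclorim 4 h arrays (-0.902, -1.094 and -1.324), although exchanging these arrays raised the calls as given above, and against the authors' scaling, quantile normalization left the component that sets them apart at 35.58% of the variance within groups, from 37.42%. Over the 18 arrays, as deviations from group means, that component had Pearson's r = 0.7268 with the signal of the spiked poly-A controls (exact permutation p = 0.00493 two-sided, 0.00986 adjusted over 2 relations; Spearman's rho 0.740, permutation p = 0.00375), 0.743 without the 2 arrays farthest from the median and 0.717 without the 2 fenclorim arrays themselves, so a difference in how much sample RNA stood against the spiked controls is a candidate explanation. RNA integrity stays open, because the relation of the component to the 3′ to 5′ ratios of 3 control transcripts was weak either way (r = -0.07803, exact permutation p = 0.752, also adjusted; rho -0.0630, permutation p = 0.821; r = 0.262 without the 2 farthest arrays). As to the amount of sample RNA, the poly-A signal also depends on how each array was scaled. Its level relative to the hybridisation controls was not tested against the component. A difference between cultures in how far the response to fenclorim had gone could also place arrays so and was not tested.

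The second pattern is that lower calls outnumbered higher ones in all 4 comparisons with acetone. Centring each array on its median gave at least 61.39% higher calls in each, as the authors' scaling would predict if it set the balance. The hybridisation controls, added at a fixed amount, were however higher on average in treated arrays. Scaling and a true fall in most transcripts therefore cannot be told apart. The share of the 100 brightest probe sets was 10.7% to 13.0% in treated groups and 10.5% and 10.9% in acetone. Under a scaling to the total signal, this share could shift all other probe sets by -0.0414 at most. The medians differed by -0.2702 to -0.495. The authors' trimmed mean, however, leaves out the brightest probe sets, these 100 among them. The share therefore cannot decide whether a few bright probe sets set the balance, and bright probe sets kept by the trimming were not tested. No biological explanation of this balance was tested.

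The third pattern is that 4714 probe sets differed between the compounds at 24 h and 1118 at 4 h. Against the authors' scaling, the ratio of these counts was at least 4.192 under quantile normalization and median centring. Against a single array, the lowest 24 h count without 1 array was 2882, without fenclorim 24 h replicate 1, and the highest was 6579, without fenclorim 24 h replicate 2, where the 4 h counts ran from 587 to 1219. The direct contrast of the compound difference between the times called 278 probe sets higher and 472 lower. Without 1 array these counts ran from 70 to 1764 and from 139 to 1255. The sign of that contrast does not tell a growing difference from a shrinking or turning one. A growing difference between the compounds with time, which the design names, remains open and is a hypothesis.

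Control probe sets outside the tested set also differed. The tests take the treated arrays as 1 set and leave aside differences between the treated groups. For the hybridisation controls the treated group means ran from 8.61 ± 0.38 (SD, n = 3) in CMP at 4 h to 9.28 ± 0.43 in fenclorim at 24 h. In acetone they were 8.44 at 4 h and 8.48 at 24 h. In the 12 treated against the 6 acetone arrays, by exact permutation tests over 18564 splits, two-sided, with 6 tests adjusted together, the hybridisation controls were higher by 0.392 (log2; 8.85 ± 0.38 SD, n = 12, against 8.46 ± 0.20, n = 6; p = 0.0271, adjusted 0.0426), with 6 treated arrays above the highest acetone array, and the poly-A controls by 0.610 (7.14 ± 0.54 against 6.53 ± 0.41; p = 0.0284, adjusted 0.0426), again with 6. The poly-A minus hybridisation difference was 0.218 (p = 0.195 by exact permutation, also adjusted). The 3′ probe set for GAPDH, a plant transcript and no spiked control, was higher by 1.01 (11.95 ± 0.37 against 10.94 ± 0.07; exact p = 5.39e-05, the smallest these splits can give, adjusted 0.000162), in 12 of 12 treated arrays. By the same exact test the median signal differed by -8.30 (30.8 ± 2.59 against 39.1 ± 2.08; p = 5.39e-05) and the share of the 100 brightest probe sets by 0.987 percentage points (p = 0.0430, adjusted 0.0516), which did not pass after adjustment.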

How the results depend on the processing

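The fit without fenclorim 24 h replicate 2 and fenclorim 4 h replicate 3 was chosen after seeing the data, and the other alternatives were planned. No called value of a named gene turned its direction under the alternatives run on it, and no set call in the 6 comparisons of groups did under the 4 run on lists, an estimated correlation, quantile normalization, no filter and the block. The set tests of the time contrasts were rerun only with an estimated correlation. Of 941 gene values per setting, those that kept their direction and their side of the threshold numbered 841 with median centring, 885 with quantile normalization, 910 with the offset, 923 without the trend, 920 without the filter, 940 with the mean of probe sets, 913 with the replicate block and 840 with only the compared arrays, and with the strict filter 750 of 757, without the fenclorim arrays that lay apart 509 of 615 and over single arrays left out 5812 of 6528. With an estimated correlation 45 set calls of the 6 comparisons of groups were lost, which was most of them. Of 174 list tests, called or not, 155 stayed on their side of the threshold with quantile normalization, 162 without the filter and 173 with the block.

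With median centring, the calls were 3474 higher and 1753 lower for fenclorim at 4 h, 4786 and 1624 at 24 h, 1612 lower for CMP at 4 h, 2476 lower at 24 h and 3205 lower for CMP against fenclorim at 24 h. By construction such centring moves all probe sets of an array together. Quantile normalization gave 2738 lower for fenclorim at 24 h. With only the compared arrays in the fit there were 2575 lower for fenclorim at 24 h, 1571 higher and 1228 lower between the compounds at 24 h, and, for the differences between times, 31 and 56 for fenclorim, 301 and 635 for CMP and 155 and 199 for CMP minus fenclorim. This fit estimates the spread from fewer arrays. Without the filter, CMP minus fenclorim between times had 178 higher, with more probe sets tested. The added fit without the fenclorim arrays that lay apart gave 947 higher between the compounds at 4 h, 4099 higher at 24 h, 1608 and 2481 for fenclorim between times and 2826 and 1867 for CMP minus fenclorim between times. Leaving out arrays because they stand apart lowers the spread by construction. The correlation of the compounds' changes at 4 h was 0.861 with the strict filter.

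Leaving out 1 array at a time, the higher and lower counts ran from 1808 to 2184 and from 2920 to 3472 for fenclorim at 4 h, 1669 to 2310 and 2950 to 4799 at 24 h, 1814 to 2011 and 2742 to 3050 for CMP at 4 h, and 2169 to 2448 and 3192 to 3587 at 24 h. Between the compounds they ran from 254 to 649 and 315 to 610 at 4 h and from 1542 to 3912 and 1340 to 2667 at 24 h. For the differences between times they ran from 46 to 772 and 100 to 1351 for fenclorim, 53 to 125 and 126 to 299 for CMP and 70 to 1764 and 139 to 1255 for CMP minus fenclorim, and for acetone from 0 to 7 and 0 to 3. The highest fenclorim and CMP minus fenclorim values there came without fenclorim 24 h replicate 2. The correlation of the compounds' changes ran from 0.801 to 0.845 at 4 h and from 0.612 to 0.744 at 24 h.

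With the replicate number as a block, the fenclorim effect between times had 88 higher, the CMP effect 85 higher, CMP minus fenclorim 146 higher and 287 lower, and acetone between times 3 higher. Of 45 pairs of arrays with the same number in different groups, 12 had deviations correlated above 0.1 (median -0.0530, range -0.508 to 0.484), and 3 of 18 arrays correlated best with their own number, so the numbers were not treated as pairs. For counts whose change the construction of the alternative does not show, the cause was not tested. No counting depth applies to arrays, and probe sets near the lowest signals have the least certain changes.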

Other observations

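The genes below were chosen after their values had been seen, and no test was added in this part. They belong to families described in the report but are not named in its results, though UGT78D1 is named under the processing. The families of the first 2 gave no set call between groups. The U-box ubiquitin ligase gene PUB24, whose product restrains immune responses, was higher by 1.99 ± 0.17 at 4 h and 0.96 ± 0.17 at 24 h of fenclorim and by 2.08 ± 0.17 and 1.97 ± 0.17 with CMP, and at 24 h it was higher with CMP than with fenclorim by 1.01 ± 0.17. The vacuolar sugar transporter gene SWEET2 was higher by 1.98 ± 0.31, 1.27 ± 0.31, 1.53 ± 0.31 and 2.16 ± 0.31 in the same order, and ATG8B, of the autophagy machinery, by 1.02 ± 0.17, 1.33 ± 0.17, 0.59 ± 0.17 and 1.22 ± 0.17. UGT78D1, a flavonol rhamnosyltransferase, was lower by limma at 4 h of fenclorim (-3.46 ± 0.40) and with CMP at 4 h (-2.34 ± 0.40) and 24 h (-1.90 ± 0.40), and stood at -0.82 ± 0.40 (adjusted p = 0.107, or -0.75 and past the threshold with an offset of 3.81 added to every signal) at 24 h of fenclorim. With that offset its change at 4 h of fenclorim was -2.65. Within sulfur and glutathione metabolism, the glutathione reductase gene GR1 was higher at 4 h with fenclorim (1.61 ± 0.23) and with CMP (1.07 ± 0.23), whereas the ATP sulfurylase gene APS3 was lower with CMP at 4 h (-0.88 ± 0.21) and 24 h (-0.98 ± 0.21) and lower with CMP than with fenclorim at 4 h (-1.25 ± 0.21). Each of these values is a log2 difference ± SE with n = 3 arrays per group, and each call held in every alternative run on it and with each array left out.

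With the authors' scaling, changes of at least 8-fold were more often increases than decreases with fenclorim at 4 h and with CMP at both times, while the lower calls outnumbered the higher ones in all 4 comparisons, a balance that turned with median centring. With fenclorim, 251 called probe sets were higher by that much and 133 lower at 4 h, against 114 and 164 at 24 h, and with CMP 306 and 90 at 4 h, against 257 and 146 at 24 h.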
